A study of Homo sapiens with 10 samples.

How the data were processed

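Transcripts of human fetal membrane explants were measured by RNA sequencing. Per the labels' protocols, explants were placed on inserts with 0.4 µm pores in medium with 10% serum, rested for 3 h in medium without serum, and then kept for 48 h with or without buprenorphine at 40 µg/ml. Total RNA was extracted with TRIzol, and libraries were made with a kit that removes ribosomal RNA, per the labels' protocols, so transcripts without a poly(A) tail are also sampled. Samples were grouped by their titles into 5 Media and 5 Buprenorphine libraries, and the labels number 5 batches with 1 library of either group in each. The batch numbers are not consecutive. That explants of 1 batch came from the same membranes is not stated in the labels. The p-values cover only the spread among these samples. Whether that is the spread within batches or between libraries is unknown, as the model terms are not given.

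Values come from 1 table of the authors' comparison of buprenorphine with media, listing 56609 gene names. Its columns hold the authors' mean signal over all libraries in normalized counts, the log2 fold change with its standard error, a test score, a p-value and an adjusted p-value. The deposited mean signal is pooled over both groups, so no level per group or per library was used. The deposited comparison names Buprenorphine before Media, so the log2 fold change was read as Buprenorphine over Media. That direction was not checked on values per library. The column names are those that DESeq2 writes, per the file headers, but neither a version nor the model terms are given in the sources used here. The submitters' processing notes name CASAVA 1.8.2 and the build hg19. The aligner, counter, gene annotation and strand setting are not given in the sources used here, so overlapping, antisense and near-identical genes are treated as uncertain.

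Several properties of the table were checked. The deposited score equalled the log2 fold change divided by its standard error to within 6.2e-15, and the deposited p-value equalled the normal two-sided p of that score to within 4.4e-16. Adjusted p-values deposited by the authors equalled a Benjamini-Hochberg adjustment over 23234 genes to within 1.3e-15. Those genes had means of at least 3.333 normalized counts, and genes with a p but no adjusted p had means of at most 3.332. XIST and Y-linked names, 508 in all, were left out of every count and result. Of the 56101 other names, 19834 were listed at 0, 36139 had a p, 12928 of these fell under the mean filter, and 23211 were tested. Where 1 group held about no reads, the fold is set by the fit: the summed normalized count over 10 libraries divided by the fold was then at most 1.0 for higher and from 0.83 to 0.84 for lower genes. Among other genes with a log2 fold beyond 4 it was at least 1.52 and 1.26, so a limit of 1.2 marked 79 tested genes, for which no fold is printed. For list medians such genes were also set at the bound that 3 reads in the lower group give. A further 128 genes had a fold change but no p.

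Depth per library was not given, but the lowest means show steps worth 1 read in 1 library. Means under 0.16 took exactly 10 distinct values over 1069 genes, 5 with positive and 5 with negative folds. Taking each step as 1 read divided by a scaling factor and by 10 libraries, the factors ranged from 0.86 to 1.23 (mean 1.11) on the side that is higher with buprenorphine. On the other side they ranged from 0.74 to 1.09 (mean 0.93), a ratio of 1.19. The means of all genes sum to 27260081 normalized counts per library. Standard errors were larger for genes with lower means: the median standard error was 0.38 on the log2 scale over all tested genes, 0.23 for genes with a mean of at least 100 and 0.80 for genes with a mean under 20.

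The design fixed before the data were examined foresaw a test on values per library, with batch as a block. As the table holds a comparison and no values per library, the fallback written with that design was used. Gene calls are the authors' deposited statistics at an adjusted p under 0.05, and no differential test of single libraries was run here. For 42 gene lists, fixed before the data were examined, the median fold was placed among 10000 random lists, each drawn from protein-coding genes in the same of 20 bins of mean count. Medians outside the central 95% were counted for lists with at least 5 tested members. List symbols were matched to the table directly or through synonyms in RefSeq gene records, and gene types came from GENCODE 29, which gave a type for 97.8% of tested genes. These references are of another build than the authors', so no coordinates are given. The adjustment over the list alone is a Benjamini-Hochberg adjustment of the authors' p-values within 1 list.

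Genes named in the text follow a rule fixed before the data were examined. It takes the 8 largest increases and 8 largest decreases among called protein-coding genes with a mean of at least 1, a fixed panel of inflammatory, opioid, sterol and stress genes, and up to 4 members per list with the smallest p. A criterion of equal direction in all batch pairs was part of the rule and could not be applied. Further list members (RIPK2, KISS1 and PSG1 in the report) were chosen after their values were seen. Some genes that the rule takes are not reported here. The 95% intervals are the deposited fold ± the normal quantile times the deposited standard error.

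The scripts were tested on simulated data. For the comparison of buprenorphine and media, folds were drawn around known values with the deposited standard errors for 23211 genes, 200 of them changed. At an adjusted p under 0.05, 52.0% of genes changed by 2-fold and 83.0% of those changed by 4-fold were recovered, and 4.3% of the 141 called genes were unchanged ones. Of 200 simulated lists of 20 unshifted genes, 4.0% lay outside the central 95% of 1000 random lists, and 100% did when shifted by 0.5. Far fewer genes were changed there than the 2802 called in the data, so these recovery rates do not carry over to the data. The noise followed the same standard errors that the test uses, so the share of unchanged genes does not check those errors. The simulated genes were independent, which real genes of a list are not. Alternatives tried were a 2-fold minimum, other adjustments and filters, a centring, a null of 2-fold, and other ways to score lists. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.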

Results

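Human fetal membranes, the amnion and chorion that enclose the fetus, were collected at term before labor and kept in culture as explants. Explants received medium alone or buprenorphine, a partial agonist of the mu opioid receptor used to treat opioid use disorder, at 40 µg/ml for 48 h. RNA was sequenced from 10 libraries, 5 of medium alone and 5 of buprenorphine, in 5 batches that each held 1 library of either group. Only the authors' gene-level comparison of buprenorphine over media was analysed here, so no value of a single library is given. The comparison asks which transcripts of the membranes change when the drug is present, with inflammatory genes as the stated interest of the series.

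Buprenorphine was accompanied by higher transcripts of chemokines, cytokines and interferon-stimulated genes, and by lower transcripts of cell cycle genes, several collagen and other matrix genes, and several trophoblast genes. Of 23211 genes with an adjusted p in the authors' deposited table, 1428 were higher and 1374 lower with buprenorphine at an adjusted p under 0.05. The called genes were 12.1% of those tested, and 1269 of the higher and 1148 of the lower genes were protein-coding. At a change of at least 2-fold, 678 genes were higher and 803 lower. Against a null of a 2-fold change, a setting chosen after seeing the data, 100 genes were higher and 66 lower. The gene with the smallest p in the authors' deposited table was IRF9, part of the transcription factor complex that interferons activate, at a log2 fold change of 1.81 ± 0.16 (SE).

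Among the 8 largest increases taken by the fixed rule, CSF2, the growth factor GM-CSF, stood at a log2 fold change of 7.03 ± 1.44 (SE) with a mean of 92.1 normalized counts in the authors' deposited table. SERPINB4, a serine protease inhibitor of squamous epithelia, stood at 6.39 ± 1.33 with a mean of 18.8 in the authors' deposited table. The chemokines CCL7 and CXCL6 and the genes MYOZ2 and LRRC55 were also called higher, with means from 7.2 to 18.9 normalized counts in the authors' deposited table. C7orf55-LUC7L2 and TRIM39-RPP21, which complete the 8, are readthrough names that share reads with their neighbours and are uncertain. Among the 8 largest decreases, TAC3, which encodes the tachykinin neurokinin B and is made by trophoblast, stood at -6.28 ± 1.96 with a mean of 386 normalized counts in the authors' deposited table. GH2, the placental growth hormone, which has near-identical paralogs, and RIBC2, SPNS3, HAPLN1, GSTA3, PAGE2B and XKR5 were called lower, with means from 5.42 to 12.2 normalized counts in the authors' deposited table. Apart from CSF2, SERPINB4 and TAC3, no fold is given for these genes, because their fitted folds equal what a group with about 0 reads gives and follow the mean count alone. Of the tested genes, 79 were of this kind, among them 38 of those called higher and 17 of those called lower.

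Gene groups were described with 42 lists fixed before the data were examined. For each list the median log2 fold change was placed among 10000 random lists of protein-coding genes matched on mean count. Of 41 lists with at least 5 tested members, 16 had a median above the 97.5th percentile and 8 below the 2.5th, against 2.1 expected of unrelated genes. Genes of a list move together, so these percentiles describe the lists and are not a test. In Fisher's exact test on called genes, chosen after seeing the data, 13 of the 41 lists differed from other protein-coding genes at an adjusted p under 0.05.

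Interferon-stimulated genes were the list with the highest share of called members. Of 32 tested, 31 were higher and 0 lower (32 and 0 adjusted over the list alone), with a median log2 fold change of 2.89 at percentile 100. OAS2 and OAS3, sensors of double-stranded RNA, stood at 5.05 ± 0.45 (SE) and 3.89 ± 0.39 in the authors' deposited table. For MX1, an antiviral GTPase, the authors' deposited table gave 4.27 ± 0.43. The corresponding adjusted p-values in the authors' deposited table were 5.9e-25 for OAS2, 2.0e-19 for OAS3 and 1.9e-19 for MX1.

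Chemokines had the highest median of the 41 lists, 3.55, at percentile 100, and the median was also 3.55 with the 3 members near 0 reads in a group set at a bound of 3 reads. Of 24 tested, 15 were higher and 1 lower, and 16 and 2 adjusted over the list alone. The neutrophil attractants CXCL1, CXCL2 and CXCL8 stood at log2 fold changes of 5.31 ± 0.52 (SE), 4.11 ± 0.46 and 3.61 ± 0.58 in the authors' deposited table. CCL5, CCL8 and CCL2, which attract monocytes and lymphocytes, stood at 4.41 ± 0.46, 5.33 ± 0.72 and 3.48 ± 0.69 in the authors' deposited table. Proinflammatory cytokines had 12 of 22 members higher and 0 lower (15 and 0 adjusted over the list alone), with a median of 2.60 at percentile 100. Among them the authors' deposited table gave IL6 at 4.89 ± 0.65, TNF at 3.65 ± 0.60, LIF at 3.75 ± 0.54, IL24 at 5.13 ± 0.87 and IL1B at 2.89 ± 0.50. Their adjusted p-values in the authors' deposited table ranged from 2.1e-11 for IL6 to 7.7e-07 for IL1B.

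Genes of the NF-kB pathway and its feedback were higher in 13 of 20 cases and lower in 0 (17 and 0 adjusted over the list alone), with a median of 1.03 at percentile 100. Here the authors' deposited table gave ICAM1, a leukocyte adhesion molecule, at 2.79 ± 0.41 (SE), BIRC3 at 2.60 ± 0.37, TRAF1 at 1.86 ± 0.27 and NFKBIZ at 1.78 ± 0.33. Inflammasome and pyroptosis genes had 6 of 18 members higher and 0 lower, the same counts adjusted over the list alone, with a median of 0.66 at percentile 100 (Fisher's exact test, adjusted p = 0.142). Apart from IL1B, the called members with the smallest p were CASP4, PANX1 and DFNA5 (gasdermin E), at 1.47 ± 0.25, 0.93 ± 0.16 and 0.75 ± 0.16 in the authors' deposited table. The sensor NLRP3 itself had a value of 0.35 ± 0.46 (95% interval -0.55 to 1.26) in the authors' deposited table, with an adjusted p of 0.741.

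Toll-like receptor signalling had 5 of 23 members higher and 0 lower, with or without adjustment over the list alone, and a median of 0.45 at percentile 99.9. Its mean, 0.30, lay within the random lists, at percentile 92.91, and Fisher's exact test gave an adjusted p of 0.599. The called members were MYD88, IRAK3, IRAK2, TICAM1 and RIPK2. Values of 1.25 ± 0.33 (SE) for the adaptor MYD88 and 1.10 ± 0.30 for the inhibitory kinase IRAK3 stood in the authors' deposited table. TLR4, the endotoxin receptor, had a value of 0.43 ± 0.35 and an adjusted p of 0.51 in the authors' deposited table. Alarmins had 7 of 14 members higher and 1 lower (7 and 4 adjusted over the list alone), with a median of 1.28 at percentile 100. S100A9 was at 2.60 ± 0.45, whereas the matrix proteoglycan BGN, which the list counts as a danger signal when released, was at -2.14 ± 0.55 in the authors' deposited table. Of 8 tested antimicrobial peptide genes, 4 were higher and 0 lower (4 and 1 adjusted over the list alone), with a median of 1.10 at percentile 99.95 (Fisher's exact test, adjusted p = 0.0744). These were PI3, LCN2, DEFB1 and RNASE7, at 4.67, 3.77, 3.57 and 1.26 in the authors' deposited table.

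**Figure D1:**
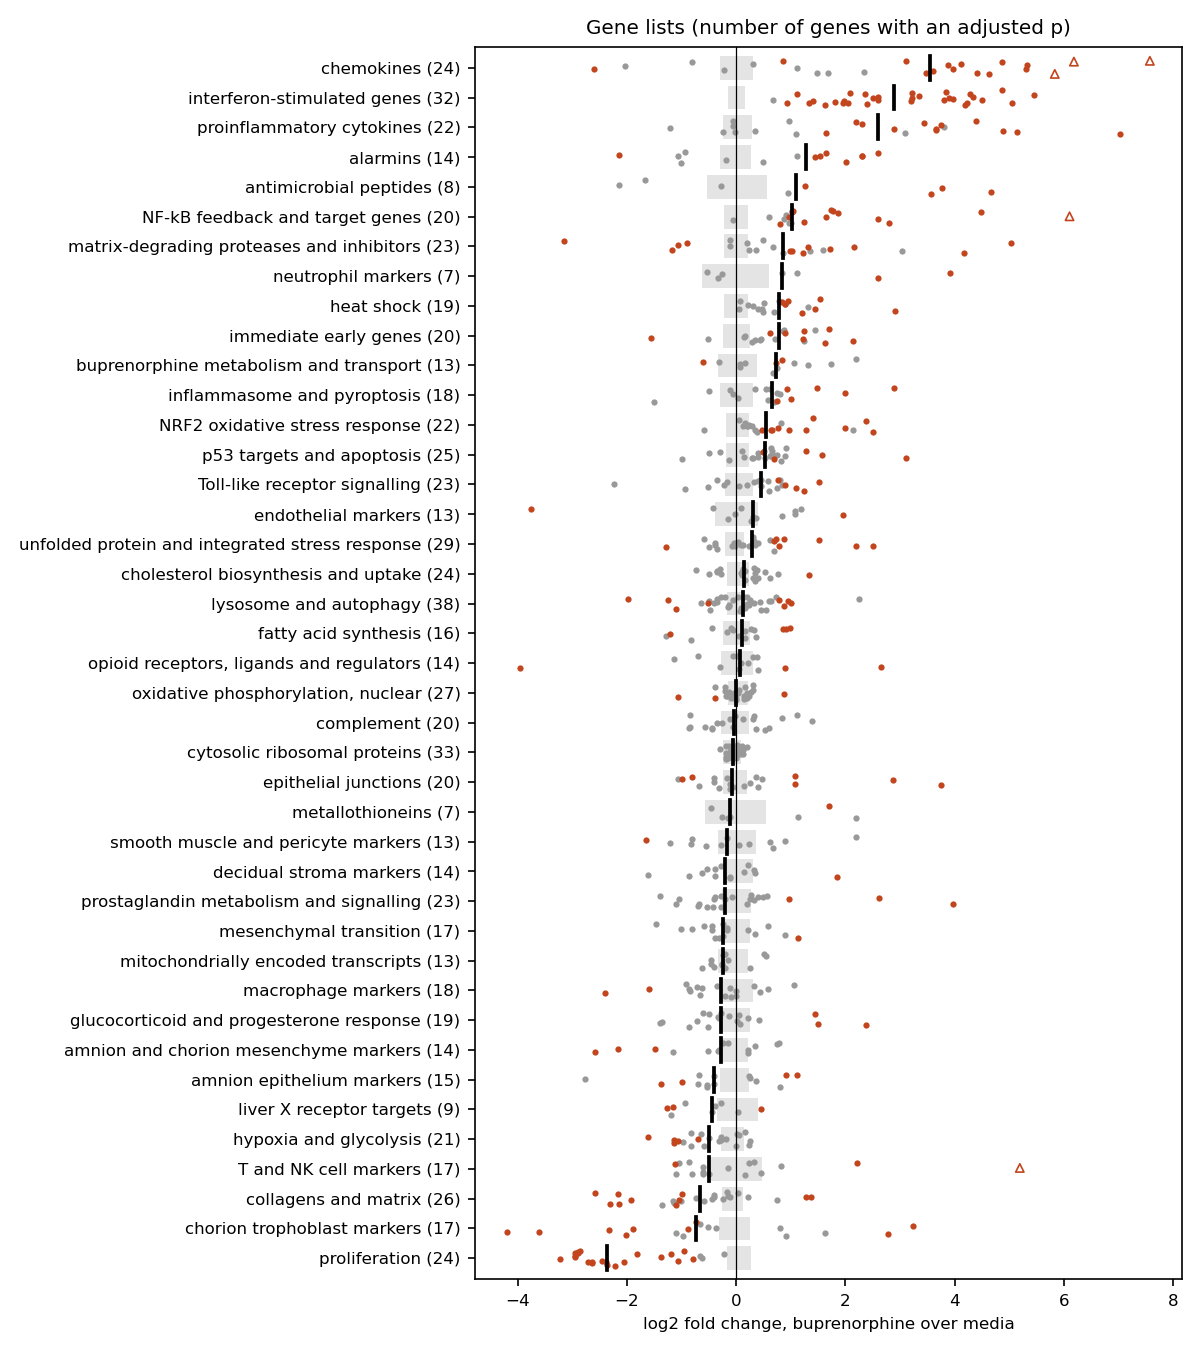
Log2 fold changes, buprenorphine over media, of the tested members of 41 gene lists, 1 point per gene, red where the adjusted p was under 0.05 and grey otherwise, with open triangles where 1 group held about 0 reads and the fold has no measured size. Black bars mark list medians and grey bands the central 95% of medians of matched random lists. Chemokines (3.55), interferon-stimulated genes (2.89) and proinflammatory cytokines (2.60) lie at the top and proliferation genes (-2.37) at the bottom.

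Matrix genes moved in both directions. Among matrix-degrading proteases and their inhibitors, 8 of 23 were higher and 4 lower (9 and 4 adjusted over the list alone), with a median of 0.86 at percentile 100. The collagenase MMP1 and the stromelysin MMP3 stood at log2 fold changes of 4.16 ± 0.96 (SE) and 5.03 ± 0.84 in the authors' deposited table, and MMP19 at 1.72 ± 0.33. In contrast, MMP11, another stromelysin, stood at -3.15 ± 0.53 in the authors' deposited table. The gelatinase MMP9 had a value of 1.58 ± 0.76 (95% interval 0.10 to 3.07) with an adjusted p of 0.172 in the authors' deposited table. Collagens and other matrix genes had 2 of 26 members higher and 8 lower (2 and 10 adjusted over the list alone), with a median of -0.67 at percentile 0. COL1A1 and COL3A1, which encode chains of fibrillar collagens, stood at -2.58 ± 0.34 and -2.16 ± 0.38 in the authors' deposited table, and COL5A1 and FBN1 at -1.11 ± 0.25 and -1.0 ± 0.24.

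In the prostaglandin list, 3 of 23 members were higher and 0 lower (3 and 1 adjusted over the list alone). PTGS2, the inducible cyclooxygenase, stood at a log2 fold change of 3.96 ± 0.49 (SE), the prostacyclin receptor PTGIR at 2.61 ± 0.35 and PTGES2 at 0.97 ± 0.24 in the authors' deposited table. The list as a whole did not stand apart: its median was -0.21, at percentile 5.22, and its mean 0.11, of the opposite sign. In the opioid list, OPRM1, the mu receptor that buprenorphine binds, was listed at 0 in the authors' deposited table. OPRL1, the nociceptin receptor, had a value of -1.13 ± 0.45 (95% interval -2.0 to -0.25) and an adjusted p of 0.0787 in the authors' deposited table. Of 14 tested opioid receptors, ligands and regulators, 2 were higher and 1 lower (2 and 3 adjusted over the list alone), with a median of 0.07 at percentile 63.86 and a mean of -0.08. The lower gene was POMC, the precursor of beta-endorphin, at -3.96 ± 0.80, and the higher ones were RGS4 at 2.65 ± 0.75 and OGFRL1 at 0.89 ± 0.29 in the authors' deposited table.

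Drug handling and lipid lists were also described. Buprenorphine metabolism and transport had 2 of 13 members higher and 1 lower (3 and 1 adjusted over the list alone), with a median of 0.73 at percentile 99.98 (Fisher's exact test, adjusted p = 0.648). Its called genes were the aryl hydrocarbon receptor AHR at 0.73 ± 0.16 (SE), CYP1B1 at 0.84 ± 0.26 and the oxidoreductase POR at -0.60 ± 0.21 in the authors' deposited table. Cholesterol biosynthesis and uptake had 1 of 24 members higher and 0 lower, on either adjustment, with a median of 0.15 at percentile 87.93. The synthase HMGCS1 had a value of 0.35 ± 0.35 (95% interval -0.33 to 1.04) in the authors' deposited table. Fatty acid synthesis had 3 of 16 higher and 1 lower on either adjustment, with a median of 0.11 at percentile 80.28. ELOVL6 and ELOVL5, fatty acid elongases, were at 0.98 and 0.85, and the synthase FASN at -1.21 in the authors' deposited table. Liver X receptor targets had 1 of 9 higher and 2 lower on either adjustment, with a median of -0.45 at percentile 0.9 (Fisher's exact test, adjusted p = 0.329). MYLIP and the cholesterol exporter ABCG1 were at -1.16 and -1.27 in the authors' deposited table. Lysosome and autophagy genes were split, with 4 of 38 higher and 4 lower (4 and 5 adjusted over the list alone) and a median of 0.12 at percentile 96.49. LPCAT1, CTSF and FNIP1 were at -1.25, -1.10 and -0.52 in the authors' deposited table.

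Several stress lists had medians above those of their random lists. Heat shock genes had 8 of 19 members higher and 0 lower (11 and 0 adjusted over the list alone), with a median of 0.79 at percentile 100. HSPA6, a strictly inducible HSP70, stood at 2.91 ± 0.47 (SE) and its cochaperone DNAJB1 at 0.89 ± 0.17 in the authors' deposited table. The near-identical HSPA1A and HSPA1B, between which reads are hard to assign, were at 1.54 and 1.45 in the authors' deposited table. NRF2 targets had 10 of 22 members higher and 0 lower (12 and 0 adjusted over the list alone), with a median of 0.55 at percentile 100. The cystine transporter SLC7A11 was at 2.50 ± 0.47, thioredoxin reductase TXNRD1 at 2.00 ± 0.42 and TXN at 1.40 ± 0.26 in the authors' deposited table. HMOX1, heme oxygenase 1, had a value of 0.22 ± 0.41 (95% interval -0.59 to 1.03) in the authors' deposited table. The unfolded protein and integrated stress response had 7 of 29 higher and 1 lower (8 and 1 adjusted over the list alone), with a median of 0.29 at percentile 99.95, but Fisher's exact test of its calls gave an adjusted p of 0.271. Among its called members, the amino acid response genes CHAC1 and ASNS were at 2.20 and 0.87, and the endoplasmic reticulum chaperone PDIA4 was at -1.28 in the authors' deposited table. DDIT3, the stress factor CHOP, had a value of 0.31 ± 0.43 and an adjusted p of 0.756 in the authors' deposited table. Genes of the p53 and apoptosis list had 5 of 25 higher and 0 lower (9 and 1 adjusted over the list alone), with a median of 0.53 at percentile 100 and an adjusted p of 0.743 in Fisher's exact test. PMAIP1, which encodes the proapoptotic protein NOXA, was at 3.10 ± 0.49 in the authors' deposited table, and TP53I3, HRK and BCL2L1 were at 1.28, 1.57 and 0.49. Immediate early genes had 7 of 20 higher and 1 lower on either adjustment, with a median of 0.78 at percentile 100. FOSL1, NR4A2 and IER2 were at 2.13, 1.62 and 0.89, whereas FOS was at -1.56 ± 0.28 in the authors' deposited table. Metallothioneins had 1 of 7 higher and 0 lower (2 and 0 adjusted over the list alone), a median of -0.12 at percentile 30.1 and a mean of 0.58. That gene was MT2A, at 1.70 ± 0.30 in the authors' deposited table.

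Proliferation genes fell together. Of 24 tested, 21 were lower and 0 higher (23 and 0 adjusted over the list alone), with a median of -2.37 at percentile 0. RRM2, a subunit of ribonucleotide reductase, stood at -2.71 ± 0.50 (SE), the spindle factor TPX2 at -2.05 ± 0.37, cyclin B1 (CCNB1) at -1.81 ± 0.33 and the replication helicase subunit MCM5 at -0.95 ± 0.17 in the authors' deposited table. Hypoxia and glycolysis genes had 5 of 21 members lower and 0 higher (6 and 0 adjusted over the list alone), with a median of -0.49 at percentile 0.01 (Fisher's exact test, adjusted p = 0.586). CA9, EGLN3, NDRG1 and the glucose transporter SLC2A1 were at -1.62, -1.14, -1.06 and -1.13 in the authors' deposited table. None of the 13 mitochondrially encoded transcripts and none of the 33 cytosolic ribosomal protein genes was called, with or without adjustment over the list alone. Their medians were -0.25 at percentile 7.79 and -0.05 at percentile 61.09, and in Fisher's exact test the ribosomal genes had fewer calls than other genes (adjusted p = 0.0227). MT-ND4 and MT-CO1, at -0.47 ± 0.17 and -0.63 ± 0.24 in the authors' deposited table, were called when adjusted over protein-coding genes only or over genes with a mean of at least 50, and MT-ND4 also after centring. Nuclear oxidative phosphorylation genes had 1 of 27 higher and 2 lower on either adjustment, with a median of 0.00 at percentile 34.7. SDHA, the flavoprotein of complex II, was at -1.06 ± 0.19, UQCRC1 at -0.39 and ATP5G1 at 0.88 in the authors' deposited table.

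**Figure D2:**
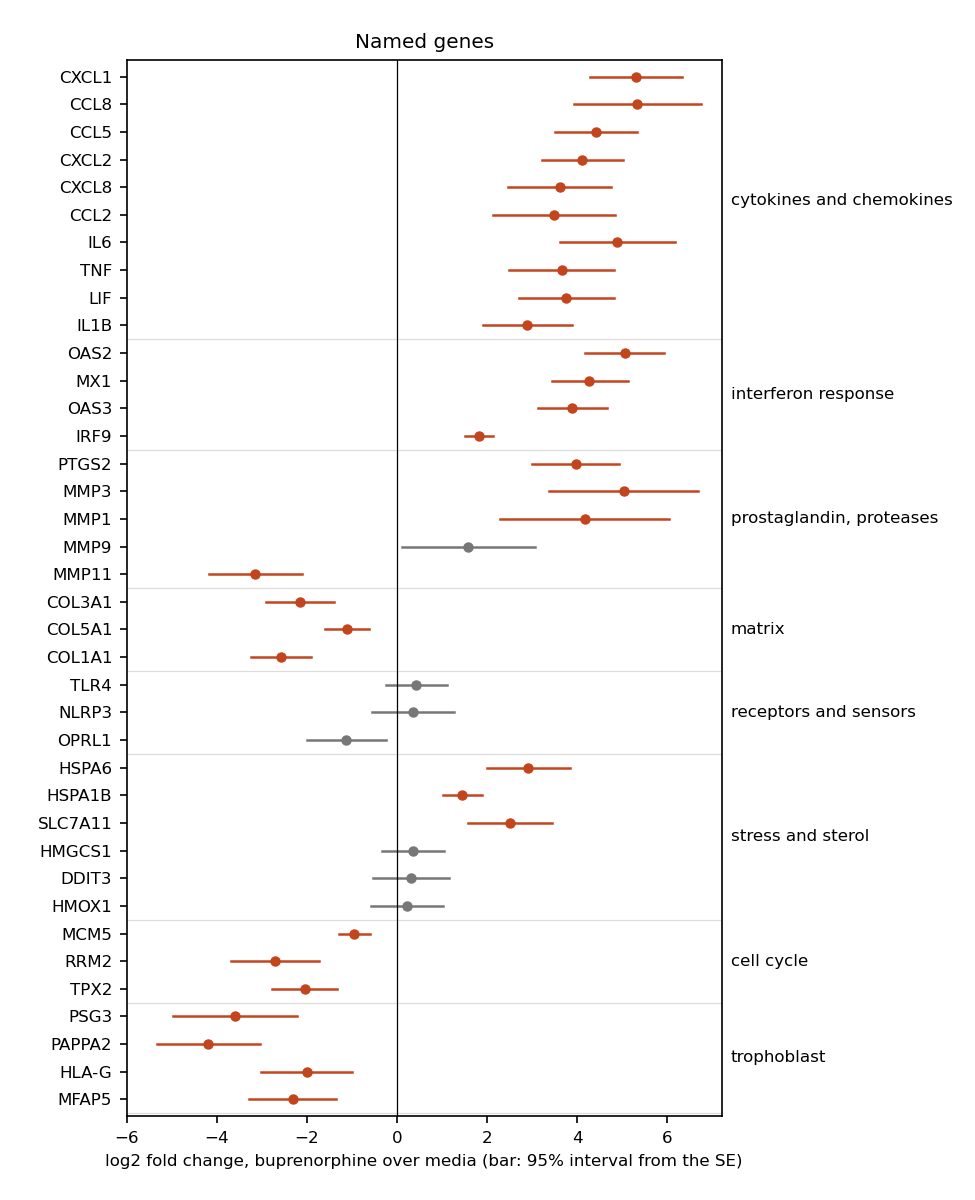
Log2 fold changes, buprenorphine over media, of genes named by the fixed rule, grouped by function, with bars for the 95% interval from the standard errors of the authors' deposited table. Red marks an adjusted p under 0.05 and grey the rest; CXCL1 (5.31) and OAS2 (5.05) lie far to the right and PAPPA2 (-4.19) far to the left, while the intervals of NLRP3, TLR4, HMGCS1, DDIT3 and HMOX1 include 0.

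Markers of the cell types of the membrane were examined beside these groups. Chorion trophoblast markers had 7 of 17 tested members lower and 2 higher on either adjustment, with a median of -0.74 at percentile 0.01. PAPPA2, a protease that cleaves insulin-like growth factor binding proteins, stood at -4.19 ± 0.58 (SE) and HLA-G, a class I molecule of extravillous trophoblast, at -2.01 ± 0.51 in the authors' deposited table. MFAP5 was at -2.32 ± 0.49 and PSG3 at -3.60 ± 0.70 in the authors' deposited table, the latter in a family of near-identical genes. The 2 higher members, KISS1 and PSG1, were at 3.23 ± 0.98 and 2.78 ± 0.72 in the authors' deposited table. PSG1 is of the same family as PSG3, so the opposite values of these 2 genes are uncertain. Of 8 tested PSG genes, 1 was higher and 1 lower, with a median of 0.27. Amnion epithelium markers had 2 of 15 members higher and 2 lower (2 and 4 adjusted over the list alone), with a median of -0.41 at percentile 0.31 and a mean of -0.31 at percentile 6.55 (Fisher's exact test, adjusted p = 0.518). KRT18 and MUC1 were at 1.12 and 0.92, and HAND1 and IGFBP3 at -1.38 and -1.0 in the authors' deposited table. Mesenchyme markers of amnion and chorion had 3 of 14 lower and 0 higher on either adjustment, with a median of -0.28 at percentile 4.59, and the 3 were COL1A1, COL3A1 and FBLN1. Decidual stroma markers had 1 of 14 higher and 0 lower on either adjustment, with a median of -0.20 at percentile 4.82, and that gene was CHI3L2, at 1.84 ± 0.45 in the authors' deposited table.

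Leukocyte markers moved in different directions. Macrophage markers had 2 of 18 lower and 0 higher on either adjustment, with a median of -0.27 at percentile 3.26. The called members were F13A1 and CSF1R, at -2.40 ± 0.58 (SE) and -1.59 ± 0.40 in the authors' deposited table. T and NK cell markers had 2 of 17 higher and 1 lower on either adjustment, with a median of -0.50 at percentile 2.17 and a mean of 0.12 at percentile 64.25 (Fisher's exact test, adjusted p = 0.87). IL7R and KLRD1 were at 2.21 and -1.12 in the authors' deposited table, and GZMB was called higher from about 0 reads in the lower group. Neutrophil markers had 2 of 7 tested members higher and 0 lower on either adjustment, with a median of 0.84 at percentile 99.32 (Fisher's exact test, adjusted p = 0.522). These were S100A9 and G0S2, at 2.60 and 3.91 in the authors' deposited table. Erythroid markers had 3 of 4 tested members higher on either adjustment. HBB was at 2.40 ± 0.73, and the near-identical HBA1 and HBA2 at 2.54 ± 0.79 and 2.59 ± 0.84 in the authors' deposited table. Endothelial markers had 1 of 13 higher and 1 lower on either adjustment, with a median of 0.30 at percentile 92.4. FLT1, a vascular endothelial growth factor receptor that trophoblast also makes, was at -3.76 ± 0.55 with a mean of 62360 normalized counts, and ROBO4 at 1.96 ± 0.65 in the authors' deposited table. Smooth muscle and pericyte markers had 1 of 13 lower and 0 higher on either adjustment, with a median of -0.17 at percentile 13.18, and that gene was NOTCH3, at -1.65 ± 0.38 in the authors' deposited table.

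The remaining lists showed changes in single genes or, for complement, no called gene. Epithelial junction genes had 4 of 20 higher and 2 lower (4 and 3 adjusted over the list alone), with a median of -0.08 at percentile 29.77 and a mean of 0.27. P-cadherin (CDH3), CLDN1, OCLN and CLDN7 were at 3.75, 2.87, 1.08 and 1.07 in the authors' deposited table. Glucocorticoid and progesterone response genes had 3 of 19 higher and 0 lower on either adjustment, although their median, -0.27, lay at percentile 2.18. The list did not stand apart by its mean, -0.05 at percentile 40.95, or over members with a mean of at least 50 normalized counts, at percentile 13.62, or in Fisher's exact test (adjusted p = 1). The 3 higher genes were AKR1C1, SGK1 and the oxytocin receptor OXTR, at 2.38 ± 0.66 (SE), 1.50 ± 0.37 and 1.44 ± 0.41 in the authors' deposited table. Mesenchymal transition genes had 1 of 17 higher and 0 lower (1 and 3 adjusted over the list alone), with a median of -0.25 at percentile 4.36, and that gene was TGFB2, at 1.13 in the authors' deposited table. No complement gene was called among 20 tested on either adjustment, with a median of -0.04 at percentile 39.83 and a mean of 0.04. CFB, at 1.38 ± 0.52 with an adjusted p of 0.0579 in the authors' deposited table, was called when adjusted over protein-coding genes only or over genes with a mean of at least 50.

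All p-values above are the authors', and the terms of their model, including whether batch entered it, are not given in the sources used here. Each fold change averages a tissue of several cell types, so a change within cells and a change in their shares are not separated by it.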

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

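These genes have a fold change but no p-value in the authors' deposited table and so enter no count of the report. All were picked after the data were seen, from genes with a mean of at least 20 normalized counts. Of the 128 genes without a p, 3 such genes had a 95% interval wholly above 2-fold higher. SPRR2A, a precursor of the cornified envelope, was listed at a log2 fold change of 8.38 ± 2.32 (SE) with a mean of 33.1 normalized counts in the authors' deposited table. BLOC1S5-TXNDC5 and ATP6V1G2-DDX39B, both readthrough names, stood at 25.35 ± 3.03 and 22.58 ± 3.03 in the authors' deposited table. These 3 folds are those of genes with about 0 reads in 1 group, set by the fit, so they give no measure of the size of the change. On the other side, 3 such genes had an interval wholly beyond 2-fold lower: SLC12A3 at -4.26 ± 1.06 with a mean of 58.2, FLRT3 at -2.91 ± 0.90 with a mean of 27.7, and 1 gene with about 0 reads in 1 group in the authors' deposited table. Why these genes have no p is not given in the sources used here. An extreme count in 1 library could carry the fold and interval of SLC12A3 or FLRT3. That cannot be checked without values per library.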

How the results depend on the processing

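Only the 2-fold minimum was among the alternatives chosen before the data were examined; the other settings below were chosen after seeing the data. Against 1428 higher and 1374 lower genes, the 2-fold minimum left 678 and 803, an adjusted p under 0.01 left 814 and 811, and a null of a 2-fold change left 100 and 66; each is a stricter criterion by construction. Adjusting over every gene with a p, centring on the median protein-coding gene (0.028 on the log2 scale), a mean of at least 50 normalized counts and protein-coding genes only kept both counts within 1.5 times, from 1249 to 1426 higher and 1194 to 1494 lower. Higher genes were 51.0% of calls, 46.5% after centring. Of 138 called named genes, 96 were no longer called against the null of 2-fold, 23 under the 2-fold minimum, 23 at an adjusted p under 0.01, 4 adjusted over every gene (C7orf55-LUC7L2, POR, FADS1 and HAND1) and 1 (FADS1) after centring. Among uncalled named genes, centring added 3 calls, a mean of at least 50 added 9 and protein-coding genes only added 8, CFB and MT-ND4 among these 8. Apart from the centring, no setting can change a sign, and the centring changed that of no called named gene. The count of 24 lists standing apart became 13 with Fisher's exact test, which counts calls of both directions together and ignores direction and small shared shifts. Of the 13, 12 were among the 24, and the other, cytosolic ribosomal proteins, had fewer calls than other genes. The 12 not kept were the inflammasome, Toll-like receptor, antimicrobial, buprenorphine metabolism, liver X receptor, unfolded protein, p53, hypoxia, glucocorticoid, amnion epithelium, neutrophil, and T and NK lists. The count stayed within 1.5 times with means, where the Toll-like receptor, glucocorticoid, amnion epithelium and T and NK lists no longer stood apart and amnion and chorion mesenchyme did. The count also stayed within 1.5 times with members near 0 reads in a group set at a bound, unmatched random lists, random lists of all tested genes, or members with a mean of at least 50. No paired analysis was possible because only a table of the comparison, with no values per library, was used here. For the same reason other normalizations, count models, pseudocounts, filters per library, set tests with an estimated correlation, leaving out each batch pair and other splits of the samples were not run. Whether 1 library or batch carries a call, and whether other groupings of the libraries give as many calls, is therefore not answered here.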

Other observations

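The lists in this part were written after the main results were seen but before their own list values were. Their examples were chosen after their values were seen. Genes already seen in the main results may be among the members. The percentiles therefore describe these lists and give no independent support. The nucleic acid sensing list, which also holds genes that are not sensors, such as the kinase IKBKE, had 8 of 14 tested members higher and 1 lower. Its median log2 fold change was 0.73 at percentile 99.99. IKBKE, SAMHD1 and ZBP1 stood at 2.29 ± 0.41 (SE), 2.21 ± 0.37 and 2.72 ± 0.85 in the authors' deposited table. Interferon transcripts themselves were near the floor: IFNB1 stood at 4.12 ± 1.23 with a mean of 4.03 normalized counts in the authors' deposited table. IFNL1 and IFNL3, with about 0 reads in the lower group, had adjusted p-values of 0.1 and 0.0886, and IFNG was listed at 0 in the authors' deposited table. Interferons and their receptors had 3 of 12 members higher and 0 lower, with a median of 0.36 at percentile 97.32. In antigen processing and presentation, 7 of 24 genes were higher and 0 lower, with a median of 0.42 at percentile 99.99 (Fisher's exact test, adjusted p = 0.161). The 7 were class I peptide supply genes and their regulator NLRC5, such as PSMB9 at 1.66 ± 0.33 and TAP1 at 1.27 ± 0.26, while the class II gene HLA-DRA had a value of -0.99 ± 0.65 in the authors' deposited table. JAK-STAT feedback genes had 3 of 21 members higher and 0 lower, with a median of 0.18 at percentile 89.76.

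Epithelial differentiation genes moved too. Among squamous and serpin B genes, 9 of 16 were higher and 0 lower, with a median of 1.57 at percentile 100. IVL, SPRR1A, KRT16 and KRT17 stood at 3.32 ± 0.75, 3.90 ± 0.92, 1.41 ± 0.34 and 1.33 ± 0.35 in the authors' deposited table. Ligands of the epidermal growth factor receptor had 1 of 6 members higher, EPGN at 2.71 ± 0.53 in the authors' deposited table, with a list median of 1.21 at percentile 99.96. Fisher's exact test on the calls did not set these ligands apart from other genes. In a scan of 271 families of protein-coding genes that share a symbol stem and have at least 8 tested members, 2 held more called genes than others in Fisher's exact test (one-sided, Benjamini-Hochberg adjusted). The test takes genes as independent, which genes of a family are not, so its p-values describe the families. HIST1H histone genes had 38 of 52 members lower and 0 higher (adjusted p = 1.3e-17, median -1.37), although near-identical copies make single values uncertain. CXCL chemokines had 7 of 13 higher and 1 lower (adjusted p = 0.0314, median 2.33). COL genes had 7 of 40 lower and 0 higher, with a median of -0.43. Calls of both directions together were not more frequent there than in other genes in that test (adjusted p = 1). Lower calls alone were not compared. Fanconi and homologous recombination genes had 13 of 20 lower and 0 higher, with a median of -1.22 at percentile 0, among them BRCA1 at -1.56 ± 0.33 and FANCD2 at -1.69 ± 0.31 in the authors' deposited table.

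Of the tests weighed below, that on DNA replication genes was chosen only after the result was seen. The first pattern is the rise of interferon-stimulated genes and chemokines, 56 tested genes with a median of 3.20. More leukocyte RNA in the treated membranes would need pan-leukocyte markers to rise alike, yet their median was -0.15 over 16 tested genes, with 1 higher and 1 lower. Neutrophil markers (median 0.84 at percentile 99.32, 2 of 7 higher) and erythroid markers (median 2.47, 3 of 4 higher) did move with the pattern, so added neutrophil or blood RNA as a part of it stays open. Only 7 of 16 listed neutrophil and 4 of 13 listed erythroid markers were tested, and the called S100A9 is also an alarmin. The trend of fold change on GC content, transcript length and mean count was small (R2 0.01, from -0.30 to 0.16 over 15313 genes), and without it the median of the 56 genes was 3.16. A response of resident cells to buprenorphine, the factor of the design, stays open as a hypothesis, and a contaminant of the drug preparation or an effect of 1 batch was not tested. CXCL12, chosen after its value was seen, is an exception among the chemokines, at -2.61 ± 0.75 in the authors' deposited table.

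The second pattern is the fall of trophoblast genes. Extravillous trophoblast genes had 11 of 18 members lower and 0 higher, with a median of -1.49 at percentile 0, among them SERPINE2 at -3.17 ± 0.58, ASCL2 at -3.09 ± 0.48 and HTRA1 at -2.85 ± 0.49 in the authors' deposited table. A loss of all trophoblast cells as the whole cause is argued against by the pan-trophoblast and cytotrophoblast genes, whose median was -0.16 (1 of 18 higher, 2 lower) where the prediction was below -1, but 4 of the 18 are also amnion markers, and over the other 14 the median was -0.27. Over members with a mean of at least 50 normalized counts the median was also -0.27, at percentile 2.32, so these stood apart as lower. The prediction also held that no called trophoblast marker would be higher, whereas KISS1 and the uncertain PSG1 were. A partial loss, or a loss or change of state of extravillous cells alone, stays open: XAGE3 and GATA3 stood at -1.26 ± 0.42 and -0.89 ± 0.30, whereas HSD3B1 had a value of 0.91 ± 0.69 in the authors' deposited table.

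The third pattern is the fall of proliferation genes. Without the same small trend on GC content, transcript length and mean count, which lay between -0.30 and 0.16, their median was -2.39, so that trend is too small to account for it. DNA replication genes outside that list were lower in 19 of 29 cases and higher in 0, with a median of -0.76, and HIST1H histone genes fell too. Fewer cells in S phase would give both falls. Both sets are cell cycle genes like those of the list, so they give no separate support for that explanation. Cycling cells that stop and cycling cells that are lost would both give these falls, and the data do not separate them.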
